A study of Drosophila melanogaster with 3 samples.

How the data were processed

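The samples were 3 biological replicates of whole Drosophila melanogaster embryos aged 0 to 14 h that carried a GFP-tagged CG17359 transgene, immunoprecipitated with an anti-GFP antibody and sequenced. Per the labels, chromatin was sheared by sonication and the assembly was dm6, which is Release 6. Arm names in the lists were those of the Release 6 reference used here, and every peak lies within the length of its arm.

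The deposit used here held 5 peak lists in narrowPeak format: 1 per replicate, 1 of the replicates pooled and 1 thresholded. Per the text files deposited with them, each replicate's peaks came from its own alignments against 1 control that all replicates shared, the pooled list came from the 3 replicates' alignments together, and the thresholded list came from the 3 replicate lists and the pooled list. The name of the thresholded list gives it as the optimal set of an irreproducible discovery rate (IDR) procedure. The aligner, the peak caller and the IDR threshold are not given in the sources used here. The labels name a control experiment without saying what was sequenced in it. The same text files also list alignments and signal tracks, which were not used here. The signal value of each peak is the authors' own, as deposited, and was used only to rank or describe peaks within a list. The -log10 q values were also deposited by the authors, ran from 0.311 to 4.12 in the pooled list, and were not used to filter. Per the deposited lists themselves, the replicate lists and the pooled list each stop at exactly 30000 peaks, so their length is set by that cap and not by a measured strength. All 7287 thresholded peaks were also pooled peaks with the same coordinates, and they were the 7287 strongest pooled peaks. Most peaks had 1 width, 390 bp in replicates 1 and 3 and in the pooled list and 330 bp in replicate 2, which limits how finely boundaries can be compared.

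The lists hold no read counts, so the depth of each library is unknown and no counting error could be given for a signal value. Errors are SDs over the 3 replicates, made from the 7287 strongest peaks of each, and binomial intervals at 95% cover counting of peaks only. Results from the thresholded list itself rest on 1 list and have no replicate error of their own.

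Before the data were examined, the tests, 27 gene lists, 14 sequence elements, a set of other settings and the rule for named genes were fixed. That rule named the nearest start site gene of the 20 strongest thresholded peaks, up to 4 members with the strongest promoter peak for each list occupied more often than its background, up to 2 for every other list with an occupied member, CG17359 itself, and the 10 leading 8-mers. Overlap was counted at 1 bp or more, against 1000 circular shifts along each arm. The fixed wording also spoke of an overlap that contains the summit, so the share of summits inside the other replicate's peak was added as an alternative. Summits were put into 7 classes in a fixed order of priority, promoter first (500 bp either side of any annotated start site), and compared with 10000 circular shifts. Arms were compared with their share of called bases by exact binomial tests. A gene was occupied if a summit lay within 500 bp of any of its start sites. Lists were tested against the other protein-coding genes (13945 on the arms in all), and RNA lists against all 18164 genes, by two-sided Fisher's exact tests. Genes that share a promoter share a peak, which that test does not model. Circular shifts were run as an alternative, but they compare a list with randomly placed summits and not with other genes. They therefore do not correct the exact test for shared peaks. Of the names on the lists, 7 were matched through an older name and 8 were left unmatched or ambiguous.

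Element matches on either strand within 50 bp of the summit were compared with a window of equal size 500 bp to one side, drawn at random with a fixed seed, by exact sign tests. The 8-mer search used one random part of the peaks for discovery and the other for testing. GC content was taken over 200 bp. Signal values of promoter and other peaks were compared by a permutation test of medians with 100000 resamples. Each family of tests was adjusted by Benjamini and Hochberg's method at 0.05. Gene models came from the Ensembl annotation of the same assembly, with annotated transposable elements left out as genes.

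Alternatives covered the overlap rule, the number of peaks taken, promoter widths of 250 and 1000 bp, the stronger part of the list, merging of peaks within 5 kb, other random placements, other windows and controls for sequence, and each replicate left out in turn. Leaving a replicate out meant the peaks among the strongest 7287 of both others, which gave 5816, 5997 and 5829 peaks without replicates 1, 2 and 3. The mean rank correlation of signal values between replicates is not reported here. Each test was first run on simulated data. On 3000 simulated peaks a planted overlap of 60% was measured as 60.7%. Of 520 random gene lists 0 were called, while a list planted at 70% occupancy in 20 draws was called in 20. Occupancy was drawn there for each gene independently, and the simulated lists were longer than many of the lists tested. That simulation therefore does not cover genes that share a peak, short lists or smaller differences. Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9 were used.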

Results

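The data were chromatin immunoprecipitation sequencing (ChIP-seq) peak lists for CG17359, a Drosophila melanogaster protein that the reference annotation calls uncharacterized and that was counted here with the ZAD family of zinc finger proteins. The flies carried a transgene for the protein fused to green fluorescent protein (GFP), and an antibody against GFP recovered the tagged protein with its DNA from whole embryos aged 0 to 14 h. All 3 biological replicates belonged to 1 group, and the design has no second condition, stage or untagged strain among the samples analysed here. The comparisons it implies are therefore between replicates, and between the places where peaks were found and the rest of the genome. Each replicate list held 30000 peaks, as did the list made from the replicates pooled, and 7287 peaks made up the authors' final thresholded list. Read counts and sequencing depth are unknown from these lists.

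The first question was whether the replicates marked the same places. Among the 7287 strongest peaks of each replicate, 80.6% ± 1.52 (SD over 3 pairs) of one replicate's peaks overlapped a peak of the other by 1 bp or more. The pair values were 79.1% for replicates 1 and 2, 82.1% for replicates 1 and 3 and 80.6% for replicates 2 and 3. After circular shifts of one list along the chromosome arms the mean overlap was between 3.15% and 3.43%, and each one-sided permutation p was 0.001, the smallest that 1000 shifts can give. A peak was shared by all 3 replicates in 72.4% ± 1.03 of cases (SD, n = 3). The strongest 7287 peaks of a single replicate recovered 87.7% ± 2.09 of the thresholded list (SD, n = 3). That list was made from the replicate lists, so its recovery is partly built in. All replicate lists were called against the same control, so a part of the overlap between them can come from that shared control.

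The strongest sites were shared by every replicate and lay mostly at promoters. Of the 20 thresholded peaks with the highest signal values, which ran from 5204 to 8514, 15 had their summit within 500 bp of an annotated transcription start site, 4 lay in introns and 1 was intergenic. No one of these 20 ranked below 25 in any replicate list. The thresholded list was made from those lists, so this agreement is partly built in. The strongest peak (3L, 19590411 to 19590840, signal value 8514) had its summit 95 bp upstream of CG14100. The second (X, 2703659 to 2704100, 8435) lay 27 bp upstream of Ugalt, a UDP-galactose transporter gene. The third (2L, 6612440 to 6612922, 8427) lay in an intron of CG11050, 1024 bp downstream of its start site. The fourth (2L, 480527 to 481319, 7966) fell in an intron, and its nearest start site, 1408 bp away, was that of cbt, which encodes the zinc finger transcription factor Cabut. The fifth (2R, 15217535 to 15217991, 7614) lay 138 bp upstream of mRpL41, a mitochondrial ribosomal protein gene.

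Others of the 20 included px at 211 bp (signal value 6829), the Polycomb group gene ph-p at 482 bp (6785), and Art3, which encodes an arginine methyltransferase, at 124 bp (6216). CG18549 at 130 bp (6103), the polynucleotide phosphorylase gene PNPase at 81 bp (5824), Fkbp14 at 131 bp (5821) and CenG1A at 98 bp (5688) followed. Chro, which encodes a chromodomain protein of polytene interbands, had its summit 89 bp inside the gene (5402). The tRNA modification gene Tcs5 at 105 bp (5311), CG13390 at 91 bp (5311), CG5611 at 111 bp (5229) and lncRNA:CR31840 at 16 bp (5315) completed the promoter sites. The remaining intronic summits lay 980 bp from the start site of the kinase gene Lk6 (5381) and 1263 bp from that of CG32772 (5204), and the intergenic one lay 891 bp upstream of lncRNA:CR45643 (5438).

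Peaks were concentrated at promoters and almost absent from coding sequence. Of the 7287 summits, 3046 (41.8%) lay within 500 bp of a start site, against 13.5% of shifted summits, a ratio of 3.09 (one-sided permutation p = 0.0001, the smallest that 10000 shifts can give). The strongest peaks of the single replicates gave 42.5% ± 0.852 (SD, n = 3). Coding exons held 15 summits, 0.206% against 13.1% of shifted summits, and 3' UTRs held 76, 1.04% against 5.08%. Intergenic sequence held 14.8% against 27.2%. These 3 shortfalls and the promoter excess passed the two-sided permutation test, each with an adjusted p of 0.00035 over 7 classes. Introns held 2956 summits, 40.6% against 39.5%, and the difference did not pass (permutation test, adjusted p = 0.267). The same test gave an adjusted p of 0.259 for 5' UTRs (0.631% against 0.782%) and 0.267 for other exons (0.961% against 0.813%). With shifts limited to 20 to 100 kb, chosen after the data were seen, the 5' UTR shortfall also passed (ratio 0.677, permutation test, adjusted p = 0.00896).

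**Figure D1:**
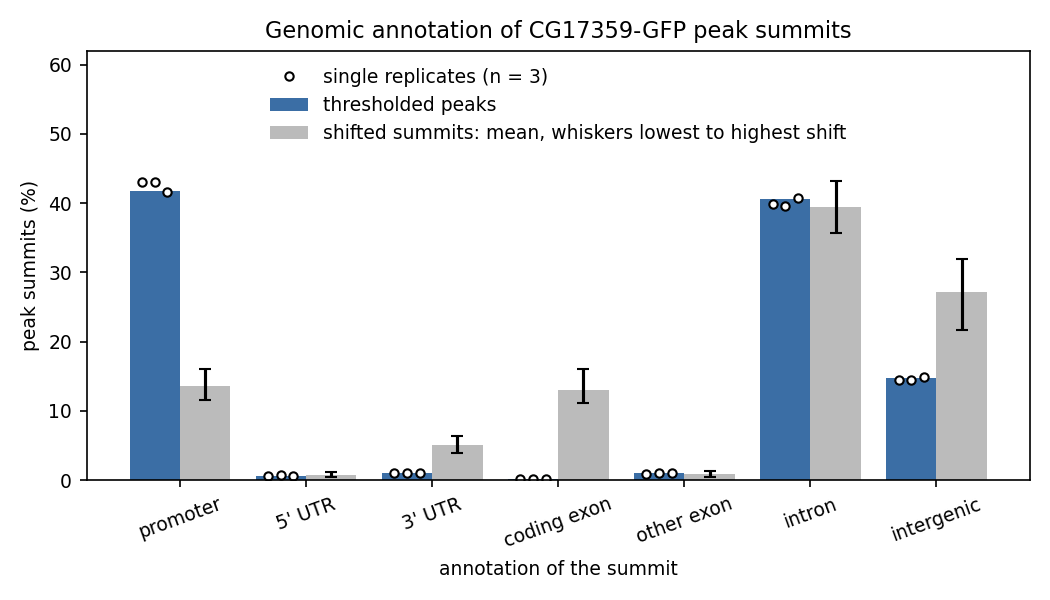
Percent of peak summits (y axis) in each annotation class (x axis) for the thresholded peaks (blue bars) and for shifted summits (grey bars, mean, with whiskers from the lowest to the highest of 10000 shifts); open circles are the strongest peaks of each of the 3 replicates. Promoters held 41.8% of summits against 13.5% of shifted ones, and coding exons 0.206% against 13.1%.

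Promoter peaks were slightly stronger than the others. Their median signal value was 408.9 over 3046 peaks against 374.4 over 4241 other peaks, a difference of 0.13 on the log2 scale (two-sided permutation test with 100000 resamples, p = 1e-05, the smallest it can give). In the replicates' own signal values for the same peaks the difference was 0.19, 0.13 and 0.15 (log2) for replicates 1, 2 and 3, with a mean of 0.16 ± 0.03 (SD, n = 3). With promoters taken as 250 bp either side of start sites the difference shrank to 0.07 (log2).

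Peaks were spread over all 6 chromosome arms in near proportion to length, with an excess on X and a shortfall on the small, largely heterochromatic chromosome 4. X held 1434 peaks, 19.7% (exact 95% binomial interval 18.8% to 20.6%) against 17.6% of bases, and the exact binomial test gave an adjusted p of 9.2e-06. Chromosome 4 held 32 peaks, 0.439% (0.301% to 0.619%) against 0.996% of bases (exact binomial test, adjusted p = 7.7e-07). Arm 2R held 17.5% against 18.9% and 3R 22.9% against 24.0%, with adjusted p of 0.00503 and 0.0380 in the exact binomial test. Arms 2L (18.2% against 17.6%) and 3L (21.3% against 20.9%) did not pass, with adjusted p of 0.188 and 0.508 in the same exact test. Among only the stronger peaks by signal value, the X excess shrank to a ratio of 1.09 and no longer passed (exact binomial test, adjusted p = 0.0529), nor did the 2R shortfall, which was also lost without replicate 3 (ratio 0.945, exact binomial test, adjusted p = 0.0645). The 3R shortfall was lost under all 6 other settings. With start sites in place of bases as the expectation, chosen after the data were seen, 5 arms passed, 2L below expectation (ratio 0.935) and 3L above (1.10), with adjusted p of 0.00747 and 4.0e-05 in the exact binomial test.

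Genes for cytoplasmic ribosomal proteins stood apart from all other gene groups examined. A promoter peak was present at 70 of 85 of them (82.4%), against 23.5% of the other protein-coding genes, an odds ratio of 15.2 (Fisher's exact test, adjusted p = 1.4e-28 over 27 lists). The replicates gave 82.7% ± 4.75 (SD, n = 3). The strongest of these promoter peaks were at RpL19 (2R, 24969284 to 24969833, signal value 2513), RpS27 (3R, 25247327 to 25247871, 2094), RpL7 (2L, 10200852 to 10201195, 1934) and RpL14 (3L, 8600772 to 8601139, 1710). All 4 were found in all 3 replicates. Their summits lay 21, 20, 36 and 33 bp from the start site.

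Position also set these genes apart, in a comparison chosen after the distances had been seen. The median distance from summit to start site was 26.0 bp at the 70 occupied ribosomal protein genes and 146 bp at the 3256 other occupied protein-coding genes (two-sided permutation test, p = 1e-05). Of the other genes, 82.8% had the summit upstream of the start site, with a median position of -134 bp. At ribosomal protein genes 62.9% were upstream, with a median position of -10.5 bp. A summit between genes that face away from each other can count as upstream of both. Of all occupied protein-coding genes, 2083 had such a neighbouring start site within 1 kb upstream, and the comparison was not adjusted for this.

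**Figure D2:**
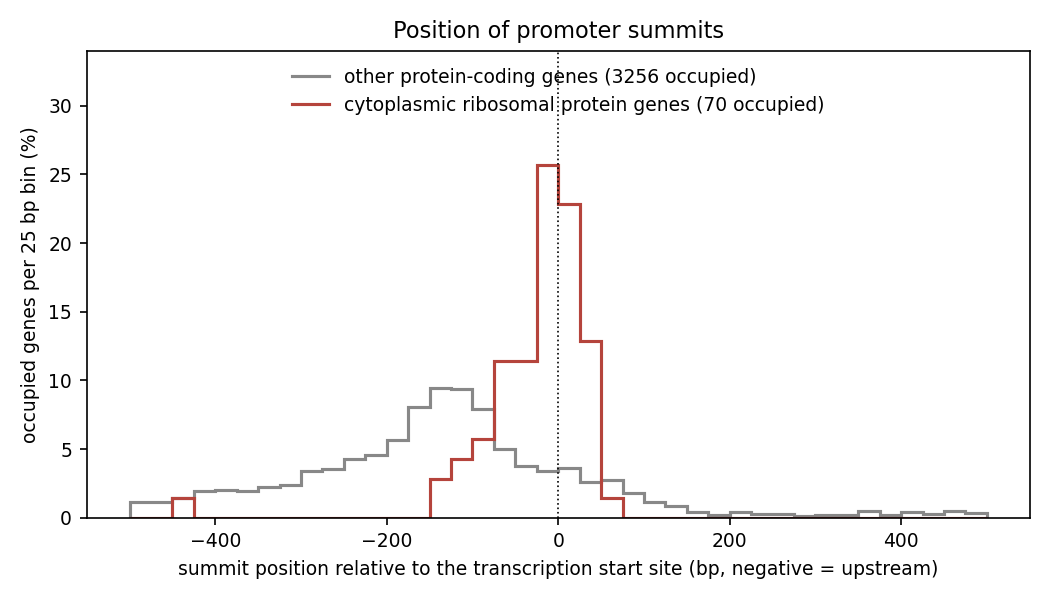
Percent of occupied genes per 25 bp bin (y axis) against the position of the promoter summit relative to the transcription start site in bp (x axis, negative is upstream), for 70 cytoplasmic ribosomal protein genes (red) and 3256 other protein-coding genes (grey). The median positions were -10.5 bp and -134 bp.

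Another 8 fixed lists passed with fewer promoter peaks than their background, among them the histone list, whose occupancy is open. None of 176 chemoreceptor genes had a promoter peak in the thresholded list, against 24.2% of other protein-coding genes (Fisher's exact test, adjusted p = 2.7e-20). Cuticle protein genes had 2 of 97, Cpr65Av (signal value 331.3) and Cpr65Ea (252.9), with an adjusted p of 1.3e-08 in the same exact test. Glue and accessory gland genes had 1 of 55, Mst85C (528.8; exact test, adjusted p = 3.4e-05), and antimicrobial peptide genes 0 of 20 (exact test, adjusted p = 0.0207). None of 111 replication-dependent histone genes had one (exact test, adjusted p = 7.6e-13). Most histone genes lie in repeated copies, and a median of 0% of the 50-mers around their start sites occurred only once on the arms. Peaks could hardly be called there, so the test cannot show whether histone genes were occupied.

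Among RNA genes, tRNA genes had peaks at 33 of 290 (11.4% against 20.6% of other genes), snoRNA genes at 22 of 269 (8.18%) and microRNA precursors at 18 of 260 (6.92%). Their adjusted p in Fisher's exact test were 0.000168, 2.0e-07 and 1.3e-08. The strongest were at tRNA:Tyr-GTA-1-8 (2564), tRNA:Leu-TAA-2-1 (824.2), snoRNA:Psi28S-2949 (1619), mir-9377 (1251) and mir-9378 (1169). The snoRNA:U49:66Da promoter window also held a peak (1710), the same peak as at RpL14. Most genes in the background of these RNA lists code for protein. Of all genes that do not, 389 of 4219 (9.22%) were occupied, a lower share than that of tRNA genes and a higher one than those of snoRNA and microRNA genes. No test was run against that background, so the shortfalls hold only against all other genes. Against shifted summits in place of other genes, the only shortfall that passed was that of chemoreceptor genes (permutation test, adjusted p = 0.0054), and tRNA genes were occupied more often than by shifted summits (adjusted p = 0.0135). Shifted summits reach few promoters of any kind, so in that comparison an excess passes easily and a shortfall hardly. With a window of 1000 bp, tRNA genes (20.3%) and snoRNA genes (24.5%) no longer passed, and the antimicrobial list passed under no other setting. In the whole pooled list, tried after the data were seen, 169 of 290 tRNA genes (58.3%) were occupied, more often than other genes (Fisher's exact test, adjusted p = 3.1e-07).

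The other 18 lists did not pass the threshold. Closest on the high side were insulator and core promoter factors (10 of 22, 45.5%, Fisher's exact test, adjusted p = 0.0587), mitochondrial ribosomal protein genes (26 of 73, adjusted p = 0.0595 in the same exact test), ZAD zinc finger genes (9 of 20) and cell cycle genes (13 of 32). The last 2 each had an adjusted p of 0.0691 in the exact test. Named members with the strongest promoter peaks were Chro (5402) and Cp190 (2503) among insulator factors, mRpL41 (7614) and mRpS10 (6216), whose peak is the one next to Art3, M1BP (879.0) and Sry-delta (620.5) among ZAD genes, and Dp (1235) and CycE (838.2) among cell cycle genes. In the whole pooled list, tried after the data were seen, insulator and core promoter factors (86.4%), mitochondrial ribosomal protein genes (69.9%) and cell cycle genes (78.1%) passed, with adjusted p of 0.000437, 0.000248 and 0.00107 in the exact test, as did oxidative phosphorylation (67.1%) and Polycomb and Trithorax group genes (70.4%), with 0.00105 and 0.0367. Mitochondrial ribosomal protein genes also passed without replicate 2 (32.9%, exact test, adjusted p = 0.0369). On the low side, chorion and yolk genes had 0 of 17 (exact test, adjusted p = 0.0504). That shortfall passed with a window of 1000 bp (exact test, adjusted p = 0.0215) and in the whole pooled list (5.88%, exact test, adjusted p = 0.000972).

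No list of developmental regulators passed against other genes in either direction, and these lists were short. Against shifted summits, neural genes (28.6% and 6.92%) and mesoderm and muscle genes (30.4% and 8.75%) were occupied more often, with adjusted p of 0.00982 and 0.0154 in the permutation test. Shifted summits reach few promoters, while 23.9% of all protein-coding genes were occupied, so a list near that share can pass this comparison. Proteasome genes (22.9% and 5.35%) also passed it, so it shows nothing particular to these lists. Peaks stood at 1 of 8 Hox genes (abd-A, 521.2), 4 of 18 maternal and gap genes (hb, 864.5, and cnc, 733.6), and 3 of 22 pair-rule and segment polarity genes (nkd, 1470, and ci, 266.5). Dorsoventral patterning genes had 5 of 24 (htl, 719.5, and ush, 354.8), neural genes 8 of 28 (elav, 2574, and E(spl)m3-HLH, 1164), and mesoderm and muscle genes 7 of 23 (sls, 1372, and tin, 1299). Gut genes had 2 of 13 (fkh, 960.0, and pnt, 341.8) and germline genes 5 of 22 (bgcn, 1311, and gcl, 451.0). Housekeeping lists outside the ribosome gave 11 of 48 for the proteasome (Rpn3, 936.9, and Rpn5, 452.6) and 22 of 76 for oxidative phosphorylation (ND-ASHI, 1553, and ND-MWFE, 1042). Polycomb and Trithorax group genes had 10 of 27 (ph-p, 6785, and brm, 2411), heat shock genes 8 of 20 (Hsp27, 3106, and Hsp83, 1581) and snRNA genes 8 of 32 (snRNA:U2:34ABb, 841.4, and snRNA:U5:63BC, 734.0). Adjusted p in Fisher's exact test ran from 0.195 to 1 over these 13 lists.

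**Figure D3:**
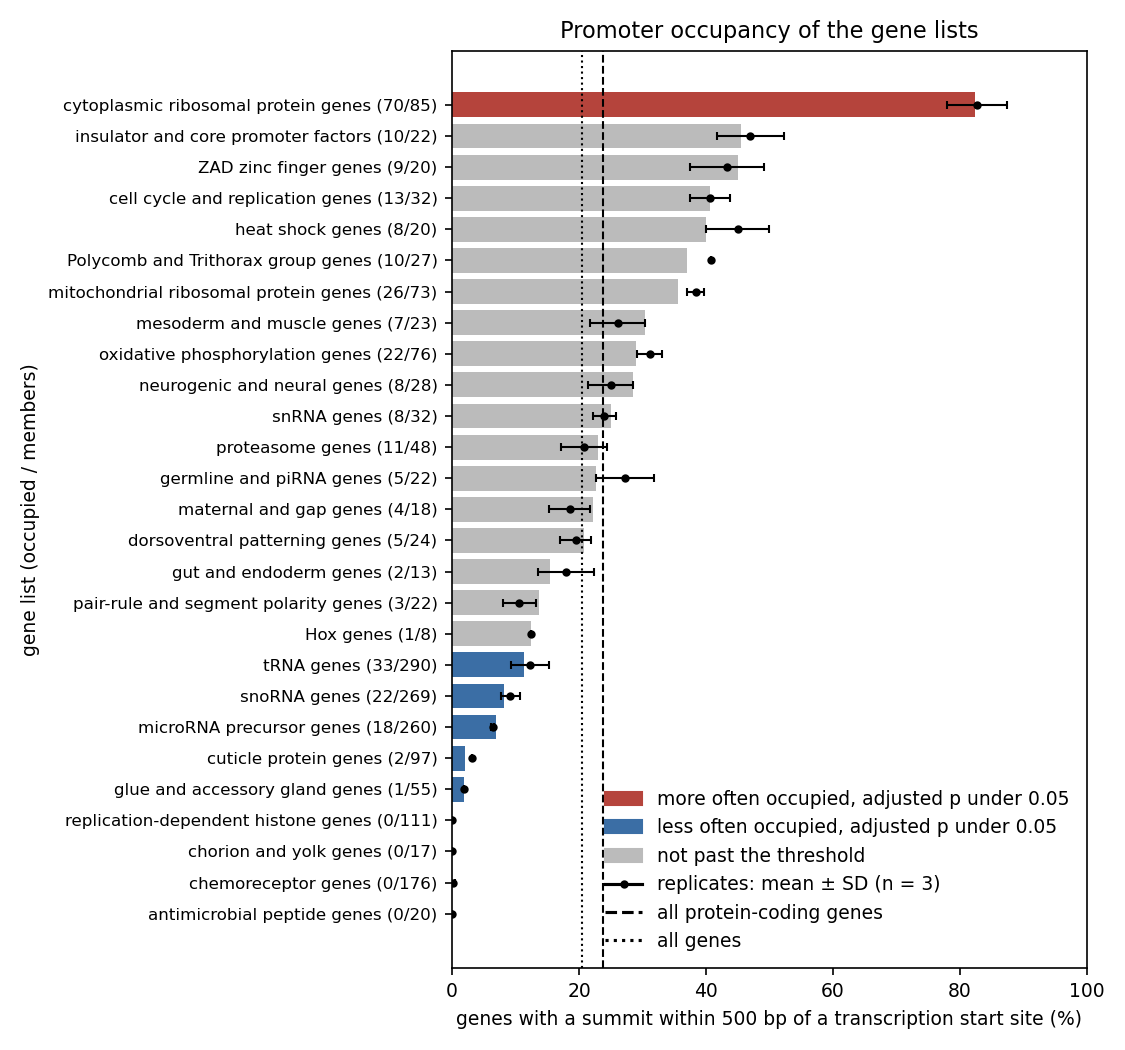
Percent of genes with a thresholded summit within 500 bp of a start site (x axis) in each of 27 gene lists (y axis, with occupied and total members). Bars are the thresholded list, black points the mean ± SD of 3 replicates, and the vertical lines mark 23.9% of all protein-coding genes (dashed) and 20.5% of all genes (dotted); cytoplasmic ribosomal protein genes stand at 82.4%.

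The sequence at summits was rich in A and T and held promoter and insulator elements. GC content in 200 bp around the summits was 35.3%, against a mean of 42.2% for shifted summits (two-sided permutation test, p = 0.0002, the smallest that 10000 shifts can give). The replicates gave 35.5% ± 0.831 (SD, n = 3). At the summit itself GC was 30.5% in the 2429 strongest peaks and 35.6% in the 2429 weakest.

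**Figure D4:**
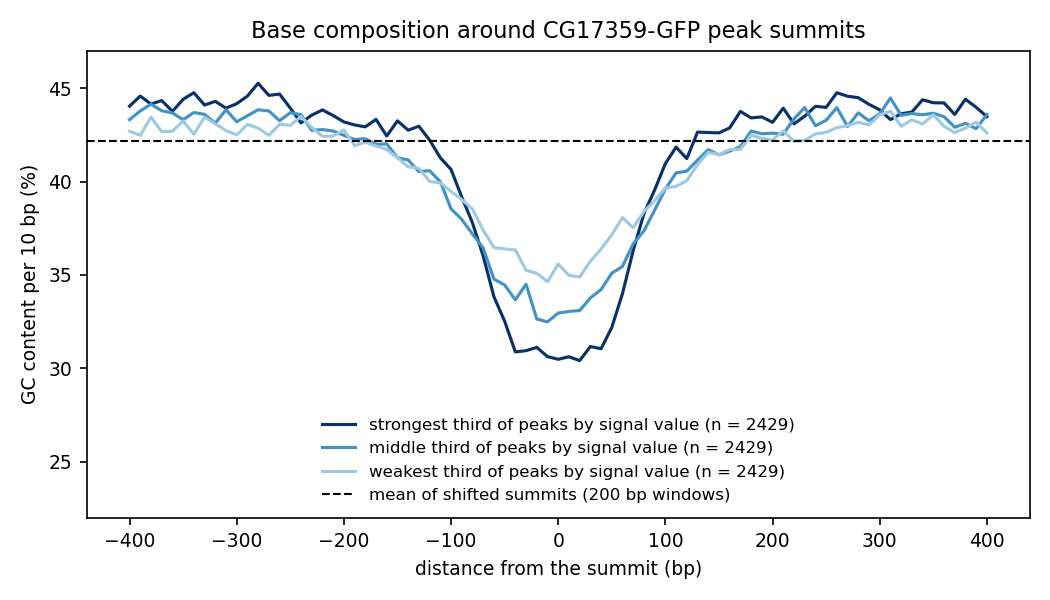
GC content per 10 bp (y axis, percent) against distance from the summit in bp (x axis) for the strongest, middle and weakest thresholded peaks by signal value (2429 each); the dashed line is the 42.2% mean of shifted summits. GC at the summit was 30.5% in the strongest set and 35.6% in the weakest.

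Of 14 known elements, 7 were more frequent within 50 bp of the summit than in a flank window 500 bp away, and 7 less. The DNA replication-related element, bound by Dref and BEAF-32, was in 75 summit windows and 14 flank windows (1.03% and 0.192%, exact sign test, adjusted p = 7.0e-11). The CTCF core was in 99 and 21 (1.36% and 0.288%, exact sign test, adjusted p = 1.2e-12), and Motif 1, bound by M1BP, in 59 and 16 (exact sign test, adjusted p = 6.4e-07). Ohler motifs 7 (4.54% and 2.83%) and 6 (0.274% and 0.110%) and Su(Hw) (1.89% and 1.34%) were also more frequent, with adjusted p of 7.0e-08, 0.0384 and 0.0128 in the exact sign test. The TATA box sequence was in 23.3% of summit and 11.2% of flank windows (exact sign test, adjusted p = 8.7e-80), but in 21.7% of shuffled summit windows with the same dinucleotides, a control chosen after the data were seen. In peaks outside promoters the DNA replication-related element was in 0.0943% of summit windows and 0.212% of flank windows, and Motif 1 in 0.236% and 0.165%, and neither passed. Ohler motif 7 passed in the opposite direction there, with 2.12% and 3.11% (exact sign test, adjusted p = 0.00835). The TATA box sequence (24.5% and 11.1%) and CTCF (1.39% and 0.283%) kept their excess there. By signal value, the excess of the DNA replication-related element was smallest in the 2429 strongest peaks (0.741% and 0.453%). It was 1.11% and 0.206% in the next 2429 and 1.24% and 0.329% in the weakest.

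Elements less frequent at summits were the CA repeat (1.496% and 3.35%), the GAGA element (1.25% and 2.51%), the E-boxes CAGGTG (2.21% and 4.20%), CACATG (3.49% and 5.01%) and CAGCTG (3.32% and 4.31%), the Pho core (13.6% and 18.3%) and the Zelda site (0.384% and 0.631%). Their adjusted p in the exact sign test ran from 1.3e-12 for the CA repeat and 2.4e-14 for Pho to 0.0474 for Zelda. Against shuffled summit windows with the same dinucleotides, none of these 7 was less frequent past the threshold. There 4 were more frequent in the summit windows than in their shuffles: CAGCTG, the CA repeat, GAGA and Pho. Their adjusted p were 1.2e-15, 9.6e-13, 3.8e-07 and 0.0303 in the exact sign test. The Su(Hw) excess was lost there. Flank windows were not shuffled, so this shows no excess at summits over other places. The CA repeat and GAGA were in 0.412% and 0.480% of shuffled windows, lower shares than in the flank windows. The Zelda shortfall was also lost with the other flank, among the stronger peaks, without replicate 1, without replicate 2 and outside promoters. At promoter peaks alone GAGA, CAGCTG and Su(Hw) did not pass, with adjusted p of 0.0522, 0.0822 and 0.342 in the exact sign test.

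**Figure D5:**
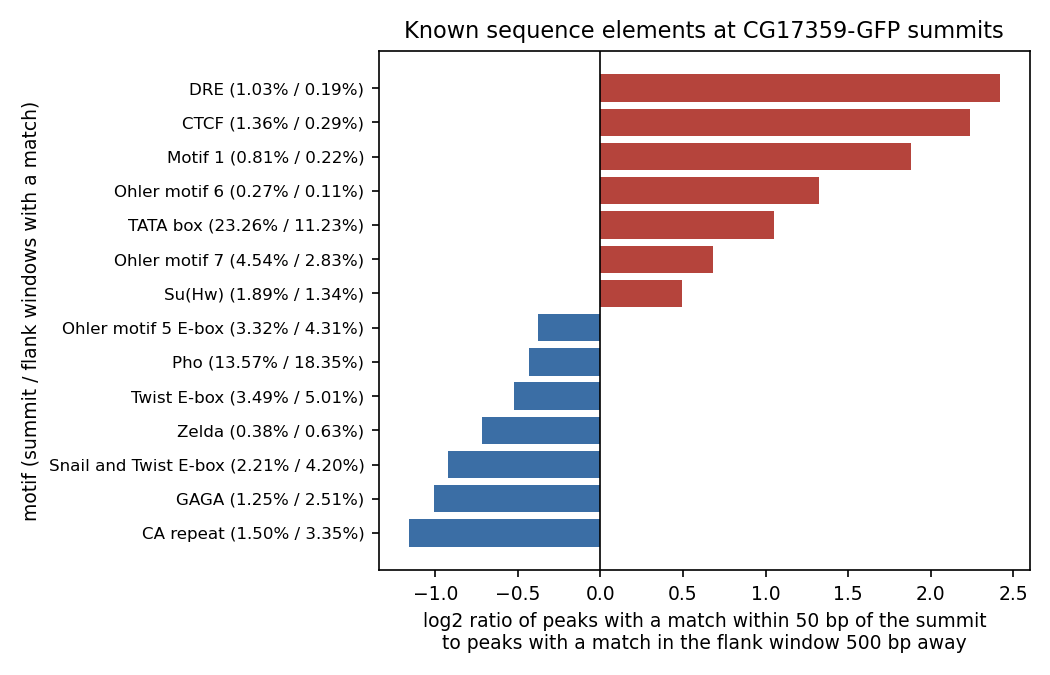
Log2 ratio of peaks with a match within 50 bp of the summit to peaks with a match in the flank window (x axis) for 14 known elements (y axis, with both percentages). The 7 elements in red were more frequent at summits, led by the DNA replication-related element at 1.03% and 0.192%, and the 7 in blue less.

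The search over 8-mers gave sequences of A and T alone. All 10 with the smallest p in one random part of the peaks passed again in the 3644 held-out peaks, all in favour of the summit. They were AAATATAT (6.28% of held-out summit windows and 2.17% of flank windows), TTAAAAAA (6.15% and 1.95%), AAAAATAT (6.45% and 2.47%), TATTTTAA (4.75% and 1.92%), AAAATATT (5.87% and 2.50%), AAAATATA (5.79% and 2.20%), ATTTTAAA (5.63% and 1.62%), TAAAATAA (5.19% and 1.84%), TTTAAAAA (6.28% and 1.98%) and ATATTTTA (5.21% and 1.81%). Their adjusted p in the held-out exact sign test ran from 2.9e-20 to 1.3e-11. Summits hold less GC than the flank, and the held-out test does not remove that difference. Against shuffled windows, 6 of the leading 10 were of A and T alone, and only 1 of the 10 named above, AAATATAT, was among them. Another of these 6, AAAAATTT, was less frequent at summits (3.38% and 6.64%). Leading sequences with C or G included AGATGGCG (1.18% and 0.0549%), CACTGAGA (0.906% and 0.137%) and CACTGTGC (0.851% and 0.0549%).

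The tagged gene's own locus held no thresholded peak. CG17359 lies on 3L at 13997900 to 13999251, on the minus strand, and none of the 7287 peaks came within 2 kb of it. Weaker peaks lay just downstream of the gene in every longer list. The pooled list had one at 13996962 to 13997351 (signal value 163.8, rank 9459 of 30000), and the strongest peaks overlapping it ranked 7409, 8038 and 11816 in replicates 1, 2 and 3. Replicate 1 also listed a peak at 13999084 to 13999473, over the start site, with rank 14507.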

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

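Chosen after the data were seen were the alternatives with start sites as the expectation, shifts by 20 to 100 kb, the whole pooled list, dinucleotide shuffles, the summit inside the other peak, the rank correlation without a replicate, and those for the distance at ribosomal protein genes. Of 100 recomputed values of the 14 main results, 14 moved; the other 86 kept their direction and side of the threshold or, for counts and correlations, stayed near the value first obtained. The tested values that stayed past their threshold still varied in size. Replicate overlap ran from 67.5% at 50% reciprocal overlap to 83.8% with fewer, stronger peaks, and promoter share from 32.3% at 250 bp to 52.4% at 1000 bp. GC content ran from 33.3% over 100 bp to 39.4% over 500 bp, and the log2 signal difference of promoter peaks from 0.07 at 250 bp to 0.18 without replicate 2. Ribosomal protein summits stayed closer to the start site, by a difference of -92.0 to -155 bp. Of the 10 leading sequences, 7 were more frequent at summits as 10-mers. Pearson's r of log2 signal between replicates, which is not a rank measure, had a mean of 0.875, and the rank correlation of the pair left without 1 replicate was 0.796 to 0.860. Recovery of the thresholded list was 70.2% at 50% reciprocal overlap, 84.9% with summits within 100 bp, 50.4% with the stronger part of each replicate's peaks (fewer peaks, so fewer can match) and 98.6% with 2 times as many. Where 4 arms had passed, 1 passed in the stronger part of the list (chromosome 4), 2 to 3 passed without 1 replicate, and 5 passed with start sites as the expectation. Ribosomal protein genes passed under every alternative. Lists occupied more often numbered 1 to 2 without 1 replicate, 7 in the whole pooled list and 13 against circular shifts, where 1 list was occupied less often. That last change follows from the construction, since shifted summits reach about 5% of promoters while other genes are occupied at about 24%. For the same reason the direction turned against shifts for Hox (12.5%), gap (22.2%), pair-rule (13.6%), dorsoventral (20.8%), gut (15.4%), proteasome (22.9%), germline (22.7%), tRNA (11.4%), snoRNA (8.18%) and microRNA genes (6.92%).

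For the rest the cause was not tested. Directions also turned for gap genes in the stronger part of the list (16.7%), dorsoventral genes at 1000 bp (33.3%), neural genes at 250 bp (7.14%), in the pooled list (39.3%) and without replicate 2 (17.9%, the lowest of 17.9% to 21.4% without 1 replicate), and mesoderm genes without replicate 1 and without replicate 3 (17.4% each, with 21.7% and no turn without replicate 2). They turned for proteasome genes at 250 bp (20.8%) and in the pooled list (54.2%), for germline genes at 250 bp (22.7%), at 1000 bp (36.4%) and without 1 replicate (22.7% to 27.3%), and for tRNA genes in the pooled list (58.3%). None of these passed except tRNA genes. The antimicrobial list lost its call under all 8 alternatives. Ratios to expected turned to 0.935 for 2L with start sites as the expectation, past the threshold, and to 0.976 for 3L in the stronger part, 0.987 with peaks merged within 5 kb and 0.992 without replicate 1 (up to 1.03, unturned, without another), and to 0.994 for introns in the stronger part. In peaks outside promoters 3 elements were more frequent at summits, and the order turned for the DNA replication-related element (0.0943%) and Ohler motif 7 (2.12%), while Ohler motif 6 was equal in both (0.141%). Against shuffled windows 0 elements were less frequent at summits past the threshold, and Zelda (0.384%), GAGA (1.25%), CAGGTG (2.21%), CAGCTG (3.32%), Pho (13.6%) and the CA repeat (1.496%) turned, and GAGA, CAGCTG, Pho and the CA repeat passed in the new direction. That control keeps the low GC of the summit window. No flank window was shuffled, so it shows no excess at summits over other places. Depth is unknown, so it could not be said what it limits.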

Other observations

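All tests in this part were chosen after the main results had been seen, and 3 of them were written after values they bear on had been seen: the comparison of ribosomal with other housekeeping genes, that of CACTG far from start sites and that of CACTG in windows matched on GC. Genes with head-to-head promoters were occupied more often than the rest. A start site of another gene on the opposite strand lay within 1 kb upstream for 5526 protein-coding genes, and 2083 of these (37.7%) were occupied, against 1243 of 8419 others (14.8%), an odds ratio of 3.49. One summit between such a pair counts for both genes, so the genes are not independent and no p is given. That counting can by itself raise the occupied share. Inside genes, the most summits lay in kirre, which encodes an adhesion protein of myoblast fusion (35 over 394.1 kb of X), followed by CG1677 with 20 and Ten-a, bun and ush with 17 each. Per 10 kb these were 0.888 in kirre, 1.60 in CG1677, 0.583 in Ten-a, 1.87 in bun and 2.64 in ush.

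The promoter peaks at cytoplasmic ribosomal protein genes differed in place from the other promoter peaks, and in GC content around the summit. The number and crowding of start sites did not account for them: no one of 10000 draws of other genes matched on both reached 70 occupied genes (highest 41, mean 27.1, permutation p = 0.0001, the smallest they can give). A signal at all housekeeping promoters alike did not either, since the odds ratio against mitochondrial ribosomal, proteasome and oxidative phosphorylation genes (59 of 197 occupied, 29.9%) was 10.9 (Fisher's exact test, p = 1.8e-16). The AT-rich sequence found at other peaks was not typical of these. The median GC of 100 bp around these 70 summits was 45.5%, which is 13.5 percentage points above that of 2406 other promoter summits (permutation test, p = 1e-05). These summits lay nearer the start site, and the windows were not matched on position. The GC difference could therefore not be told apart from the difference in place. Whether the tagged protein is held at these start sites or very strong transcription draws signal there may not be told from peak lists alone, since expression and an untagged control were not analysed here, and no biological explanation was tested.

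Around the summits the AT-rich centre ended in a recurring sequence. CACTG, on either strand, lay over 40 and up to 120 bp from the summit in 43.6% of thresholded peaks, against 26.8% over 180 and up to 260 bp away. The sequence and the zones were chosen from these same peaks, so no p is given for that difference. CACTG stood on both sides in 9.44% of peaks, against 7.04% if the sides were independent (odds ratio 1.82). These are the same peaks, so no p is given here either. Mixing peaks with unlike border shares can also raise the share with both sides. Among 8-mers compared with shuffled windows of 150 bp either side, CACTGAGA was in 5.60% of held-out windows and 0.659% of shuffled ones, and CACTGTGC in 4.97% and 0.714%. In the 18513 pooled peaks below the threshold and over 1000 bp from any thresholded summit the pattern was weaker, with a border share of 29.9% against 25.8% further out and both sides in 3.26% against 2.75%. The border share was 48.3% in the 2429 strongest peaks, 42.9% in the next 2429 and 39.8% in the weakest.

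Of 3 ordinary sources of this pattern, the values argue against an initiator at annotated start sites and against GC content alone, and leave transposable elements undecided. A core promoter initiator would be missing far from start sites. At 3465 peaks over 1000 bp from any annotated start site, the border share was still 1.79 times the outer share (46.9% and 26.1%). These peaks are among those from which the sequence and the zones were chosen, so no p is given. Copies of transposable elements would raise the share of summits inside them, which was 0.233% against 5.81% of shifted summits (one-sided permutation p = 1). Few peaks thus lay in annotated elements. Reads that copies share may keep peaks out of them, however, so that test could not decide whether such copies were a source. GC content alone would leave peaks like other windows of the same GC. Windows over 1000 bp from any pooled summit were matched to each peak on GC of the centre and the borders. They were not matched on dinucleotides or annotation class. They had CACTG at the borders in 21.7%, against 43.6% of thresholded peaks (odds ratio 2.80), again without a p since the sequence came from these peaks. For the 18513 weaker pooled peaks, which played no part in that choice, the shares were 23.2% of matched windows and 29.9% of peaks (Fisher's exact test, odds ratio 1.41, p = 4.7e-48).

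A hypothesis was that the border sequences have a fixed orientation, tested in the same 18513 weaker peaks, which played no part in finding them. TCTCAGTG border matches had the TCTC end toward the summit in 82.2% (231 of 281, exact binomial test, p = 5.7e-29), but GCACAGTG had its first base toward the summit in only 30.3% (71 of 234, exact binomial test, p = 1.7e-09). Each sequence could thus have a preferred orientation. Read outward from the summit, the more frequent forms were TCTCAGTG and CACTGTGC, in which the shared CAGTG faces opposite ways. Set 1 base apart, however, both forms hold CWCWGTG in the same direction, where W is A or T. CAGTG alone therefore cannot set the direction, and whether 1 common sequence is read in 1 orientation was left open. Nothing here shows that CG17359 itself reads either sequence, and no biological explanation was tested.

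For lists with few promoter peaks, the reads that copies share may account for the histone genes. A median of 0% of the 50-mers within 250 bp of the start sites of 111 histone genes occurred once on the arms, and the pooled list held no peak at any of them, so their occupancy is open. For the 348 chemoreceptor, cuticle, glue and antimicrobial genes the median was 100%, as it was for 500 other protein-coding genes, which argues against shared reads there. The tRNA, snoRNA and microRNA genes were not included in this test. No biological explanation was tested for any of these lists.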
